A study of Arabidopsis thaliana with 8 samples.

How the data were processed

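Whole-root RNA from 2 genotypes (wild type and pye-1) on 2 media (with and without iron) was hybridised to 8 Affymetrix Arabidopsis arrays with 1 colour, 2 per group. Per the labels' protocols, RNA was extracted with a column kit, amplified in 1 cycle, labelled with biotin, and each replicate came from about 320 roots cut just below the hypocotyl after 24 h on the media. The labels put 0.3 mM ferrozine in the medium without iron. Per the submitters' processing notes, the deposited signal intensities are MAS5 values, the Affymetrix algorithm that combines perfect-match and mismatch probes of a probe set into 1 number. Its version is not given in the sources used here. The values are on a linear scale, from 0.0200 to 21897, and the mean of each array after 2% of values were trimmed at each end was 250.02, so the authors' values had been scaled to a common target. MAS5 corrects each probe for its mismatch signal, and dim probe sets scatter widely on the log2 scale. The deposited table used here carries no detection calls.

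Samples were put in groups by the genotype and medium in the labels, with replicate numbers from the sample titles. The log2 of each deposited value was taken without a pseudocount and with no further normalization. The 64 control probe sets of the array maker were left out of the 22810, as was the 30% of the other 22746 with the lowest mean log2 signal (a mean signal below 23.3), which left 15922. Probe sets were named through the platform annotation given, updated by locus to a gene table of the TAIR10.1 assembly. Of the 22746 probe sets, 13513 name 1 gene, 503 name several and 8730 (38.4%) have no name here, among them probe sets of well-studied genes. Of the tested probe sets, 8793 (55.2%) name 1 gene. Probe sets without a name are given by their array ID after the word probe and a hyphen. Counts of probe sets therefore cover all tested probe sets, while statements on genes cover the named part. No coordinates are given because the sources used here name no genome build for the array.

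Changes were tested with limma 3.58.1 in R 4.3.3 (lmFit with 1 mean per group over all 8 arrays, contrasts, and eBayes with an intensity trend). The 4 residual degrees of freedom were joined by 6.32 from the prior. The 5 contrasts were the iron response in each genotype, pye-1 against wild type on each medium, and their interaction. P-values were adjusted by Benjamini-Hochberg within a contrast, with a threshold of 0.05. An exact permutation test of 2 against 2 arrays cannot go below p = 0.333, so none was run. No group is large enough to look for single outlying arrays or to regroup the samples. For named genes the rule was PYE, then up to 10 single-gene probe sets with the largest rise and 10 with the largest fall per contrast whose groups did not overlap (no such condition for the interaction), then the 2 to 4 members with the smallest p of each gene list described, and any tested member of the uptake and regulator lists. The lists, the tests, the rule and the alternatives were set before the data were examined, except where stated.

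Gene lists were tested with camera in limma at a preset correlation of 0.01 between genes, and again with a correlation estimated from the residuals. Of the 28 lists fixed, holding 417 loci, 64 loci had a named probe set and 55 were tested. So 10 lists had at least 3 tested probe sets, 8 had 1 or 2 and 10 had none, 7 of them because no probe set is named for any member. Genes bound by PYE as named by the study are among the lists with none, as are nicotianamine and ligand transport, xylem, phloem and root cap markers, and phosphate and nitrate genes. Lists of low-oxygen, glucosinolate and clock genes were compiled after the leading genes had been seen.

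The control level of an array is the highest signal on it among 27 bacterial control probe sets, which were taken as not spiked. It ran from 11.7 to 23.7 signal units over the arrays. A probe set was read as at the control level on an array when it lay at or under this signal. That level was chosen after seeing the data. A fold against a group at the control level on both arrays is given as a bound, the bright group's mean over the mean of, per array, the higher of the control level and the probe set's own signal.

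Replicate numbers are shared by all 4 groups in the labels, which do not call them a day or batch. Deviations of same-numbered arrays from their group means correlated at 0.178 to 0.302 in all 6 pairs of groups, and the 25S ribosomal RNA control was 6.97 to 10.2 times higher on replicate 2 arrays. The replicate number was therefore treated as a batch that the data show, and fitted as a block in an alternative (3 residual degrees of freedom, 9.41 from the prior). The blocked value stands beside a result where it changes the call or moves a count by more than 1.5 times. The ratios of 3' to 5' control probe sets were 1.28 to 1.58 for GAPDH, 3.71 to 5.40 for actin and 2.60 to 3.42 for ubiquitin on the 8 arrays.

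The steps were checked on simulated data, with 50 probe sets changed at each fold among 15922 and no replicate effect. For the response in wild type, 28% of changes of 1.5-fold, 72% of 2-fold, 96% of 4-fold and 100% of 8-fold were recovered. In pye-1 these shares were 18%, 72%, 100% and 100%, for pye-1 against wild type with iron 20%, 60%, 92% and 100%, without iron 20%, 78%, 94% and 100%, and for the interaction 6%, 28%, 86% and 94%. Unchanged probe sets made up 11 of 163, 13 of 161, 10 of 149, 11 of 161 and 9 of 119 calls in the same order, and 8 of 156, 12 of 159, 14 of 154, 17 of 167 and 11 of 121 with the block, each a share above the threshold of 0.05. Alternatives were quantile normalization, centring on each array's median, no filter or one at 50%, a pseudocount of 12.8 signal units, eBayes without the trend or with a robust prior, the 4 compared arrays alone, probe sets that match several genes left out, array weights, the replicate block, each array left out in turn, a threshold with a change of at least 1.5-fold, and, added after seeing the data, signals under the control level of their array raised to it. With an array left out, the lone array of its group is assumed to vary like the others. These fits hold no replicate term, so changes that involve this group also carry part of the difference between replicate numbers. Figures were drawn with matplotlib 3.10.9, and tables joined with pandas 2.3.3, in Python 3.11.15.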

Results

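Gene expression was measured in whole roots of Arabidopsis thaliana (Columbia) in wild type and in pye-1, a mutant of POPEYE (PYE), a basic helix-loop-helix transcription factor of the iron-deficiency response. Plants 7 days after germination had been moved for 24 h to medium with iron (+Fe) or to medium without iron that held 0.3 mM ferrozine, a chelator of ferrous iron (-Fe). The 8 arrays form 4 groups of 2, and the labels describe the 2 arrays of a group as biological replicates of about 320 roots each. Median signal lay between 91.4 and 97.6 on the 8 arrays, and arrays of the same group correlated at 0.975 to 0.981 across probe sets, against 0.957 to 0.979 for arrays of different groups. The 25S ribosomal RNA control read 242 to 565 on the 4 replicate 1 arrays and 1691 to 4047 on the 4 replicate 2 arrays, and the second principal component (19.1% of the variance) separated the replicate numbers. Within a replicate number there is 1 array per group, so the change in each replicate number is given without a test. All changes below are log2 differences of 2 arrays against 2 arrays, ± the standard error of the limma fit over all 8 arrays, with Benjamini-Hochberg adjusted p. The small number of arrays limits the precision.

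PYE itself read 56.7 and 65.1 signal units in wild type with iron and 138 and 149 without iron. On the pye-1 arrays it read 19.1 and 15.0 with iron and 25 and 28.2 without iron. The control level, the highest signal among bacterial control probe sets taken as not spiked, ran from 11.7 to 23.7 over all arrays. On the same pye-1 arrays it was 18.7 and 12.8 with iron and 19.3 and 11.7 without. The PYE readings lay above these levels, but those with iron lay close to them, which limits the comparisons that use them. Without iron, PYE was lower in pye-1 by a log2 change of -2.44 ± 0.27 (adjusted p = 0.00311), and the difference was -2.47 in replicate 1 and -2.41 in replicate 2. With iron the difference was -1.84 ± 0.27, which did not pass (adjusted p = 0.0630) but did with replicate number as a block (adjusted p = 0.0171). In wild type, PYE had a change of 1.24 ± 0.27 without iron (adjusted p = 0.0819, and 0.0384 with the block). Leaving out wild-type replicate 1 or 2 without iron ended the call of the -Fe difference (adjusted p = 0.0613 and 0.0616, with changes of -2.49 and -2.38). Where the probe set lies relative to the pye-1 insertion is not given in the sources used here, so the reading checks the labels only as far as these probes see the disrupted transcript.

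The comparison of wild-type roots without and with iron asks which transcripts respond to 24 h of iron deficiency. Of the 5 measured genes of FIT-dependent iron uptake, named after the transcription factor that most of this set depends on, 4 rose. AT3G12900, an oxygenase of coumarin synthesis, was at the control level on both +Fe arrays and reached a mean log2 signal of 10.11 ± 0.17 (SD, n = 2) without iron, at least 56.7-fold higher (adjusted p = 1.88e-06). AT3G58060, a metal tolerance protein that carries manganese, rose by 4.13 ± 0.43 (3.69 with signals raised to the control level, which its signal on 1 +Fe array did not reach), the kelch-repeat gene AT3G07720 by 3.79 ± 0.21, and BGLU42, a beta-glucosidase that releases coumarins, by 2.13 ± 0.13. AT3G13610, which makes the precursor of scopoletin, had a change of 0.77 ± 0.20 (adjusted p = 0.154, and 0.0134 with the block). The uptake genes rose as a set (camera adjusted p = 1.44e-20, and adjusted p = 0.00622 with an estimated correlation). With signals under the control level raised to it the mean was 3.24, 3.18 in replicate 1 and 3.30 in replicate 2 (adjusted p = 9.22e-23, and 0.00508 with an estimated correlation). Adjusted over the list alone, all 5 were past the threshold.

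Regulators of iron deficiency also rose in wild type. Among 11 probe sets, 5 rose and 6 did not pass, or 6 adjusted over the list alone. BHLH101, a basic helix-loop-helix factor of the iron response, rose by 3.63 ± 0.28 (3.51 with signals raised to the control level), and AT1G47400, which encodes a small iron-signalling peptide, by 3.75 ± 0.19. Both probe sets of AT1G74770, a hemerythrin-domain ubiquitin ligase, rose, by 2.29 ± 0.31 and 1.98 ± 0.17, and the related AT1G18910 rose by 0.89 ± 0.16. ILR3, bHLH34, bHLH104, bHLH115 and bHLH121, which act upstream in the same network, had changes of -0.24 to 0.15. As a set the mean was 1.24, 1.11 in replicate 1 and 1.37 in replicate 2 (adjusted p = 3.19e-10, and 0.0166 with an estimated correlation). The set lost its call when the block and the estimated correlation were combined (adjusted p = 0.0574).

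Of 5 genes of phenylpropanoid and coumarin synthesis, 1 rose, AT3G12900 again, and 4 were past the threshold adjusted over the list alone. The list rose as a set (adjusted p = 7.66e-09, and 0.0166 with an estimated correlation). With signals raised to the control level the mean was 1.56, 1.52 in replicate 1 and 1.59 in replicate 2 (adjusted p = 5.97e-09, and 0.0399 with an estimated correlation), but AT3G12900 and AT3G13610 also belong to the uptake list. The remaining 3, HCT, CCR2 and AT1G28680, had changes of 0.20, 0.49 and 0.50, with a mean of 0.40. Photosynthesis genes, measured here as markers of green tissue, had a mean of -0.38, with -0.50 in replicate 1 and -0.27 in replicate 2. They fell as a set (adjusted p = 0.00505), which did not hold with an estimated correlation (adjusted p = 0.0876) or without wild-type replicate 1 with iron (adjusted p = 0.0614, mean -0.27). Among its 4 members only PSAN, a photosystem I subunit, fell by 0.93, and LHCB4.1 and RCA had changes of -0.37 and -0.36. Of the root hair markers, EXPA18 fell by 0.93 and EXPA7 had a change of -0.39. SAPX, an ascorbate peroxidase that carries heme iron, fell by 0.89. The other 6 lists tested (zinc, copper and manganese transport, tetrapyrrole and heme synthesis, iron-sulfur cluster assembly, dividing cells, oxidative stress and reference genes) gave adjusted p from 0.319 to 0.828.

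Outside the lists, the pectin methylesterase gene ATPMEPCRB rose by 4.90 ± 0.63, the amino acid transporter family gene AT5G38820 by 3.75 ± 0.21, AT3G61930 by 3.20 ± 0.14 and AT3G06890 by 2.96 ± 0.18. AT1G73120 rose by 5.10 ± 0.77, but its signal in wild-type replicate 2 with iron lay under the control level. It rose by 4.16 with signals raised to that level and by 3.41 without that array. Among named genes the peroxidases AT3G49960 and AT1G34510 fell, with changes of -4.29 ± 0.34 and -3.14 ± 0.33. Decreases were also called for the sugar transporter SWEET11 (-1.3 ± 0.20), the cellulose synthase-like CSLC12 (-1.99 ± 0.37), the cytochrome P450 CYP718 (-1.84 ± 0.30), AT2G41810 (-1.88 ± 0.24) and AT1G19530 (-1.90 ± 0.33). AT4G25790 and AT4G30320, which belong to the same family of secreted proteins, had changes of -1.45 and -1.29, and the polygalacturonase-like AT2G43890 of -1.36, all past the threshold. Of the probe sets that no gene name was given for, chosen after their values were seen, probe-253502_at was at least 54.8-fold higher, probe-254550_at rose by 5.99, probe-263376_at fell by 4.33 and probe-254818_at fell by 2.72. The signals of AT3G49960 in wild-type replicate 1 and of probe-263376_at in wild-type replicate 2 without iron lay under the control level. With signals raised to it the changes were -4.17 and -3.10, and without the array concerned -3.66 and -3.23. Without wild-type replicate 1 or 2 with iron, AT1G19530 had changes of -1.30 and -2.50 and probe-254550_at of 6.89 and 5.09.

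In all, 155 of 15922 probe sets changed in wild type, 89 higher and 66 lower. Across all tested probe sets, the changes in replicate 1 and 2 correlated at 0.45. With the replicate block the count was 485, 250 higher and 235 lower. Without wild-type replicate 1 with iron, or wild-type replicate 1 or 2 without iron, it was 89, 89 and 83, and 90 without the intensity trend. The rises of AT3G12900, AT3G58060, AT3G07720, BGLU42, BHLH101, AT1G47400, AT1G74770, ATPMEPCRB, AT5G38820, AT3G61930 and AT3G06890 and the falls of AT3G49960, AT1G34510 and AT2G41810 passed in each of the 8 fits that left out an array. CSLC12, SWEET11, CYP718, AT1G19530, EXPA18, PSAN, SAPX, AT1G73120, AT1G18910, AT4G25790, AT4G30320, AT2G43890, probe-263376_at and probe-254818_at missed the threshold without at least one of the 4 arrays compared, with adjusted p of up to 0.347, for CSLC12 without wild-type replicate 1 with iron.

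**Figure D1:**
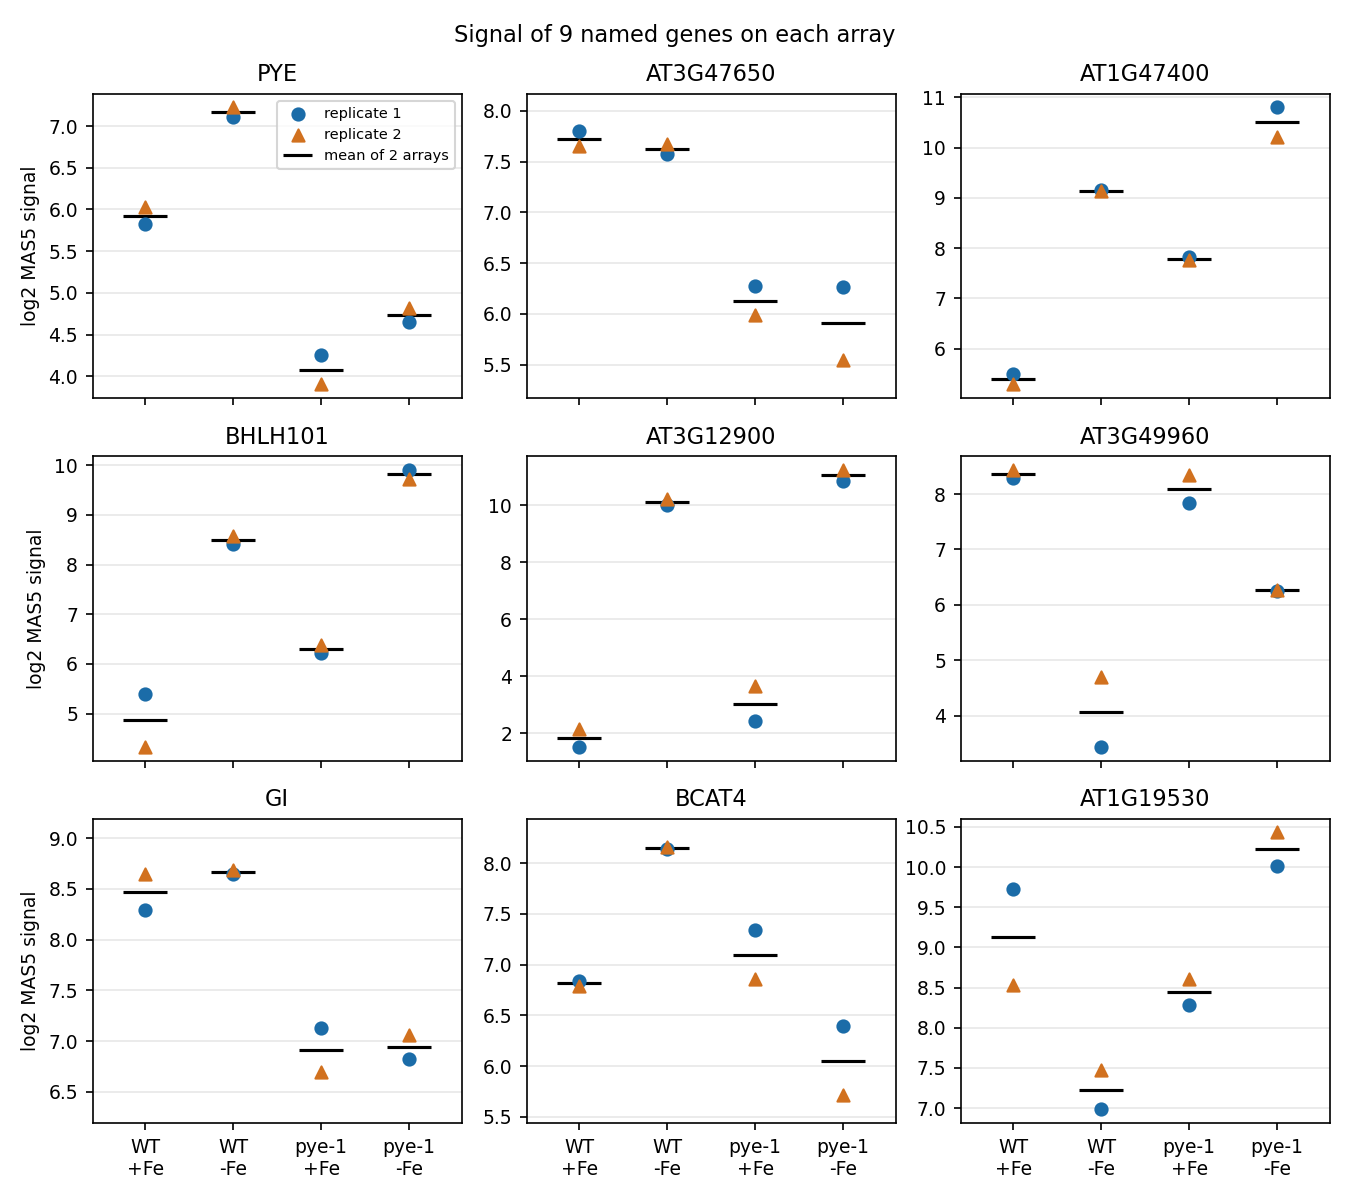
Log2 MAS5 signal (vertical axis, a separate scale per panel) of 9 named genes in the 4 groups (horizontal axis). Circles are replicate 1, triangles replicate 2 and bars the mean of the 2 arrays; PYE and AT3G47650 are lower on all 4 pye-1 arrays than on the 4 wild-type arrays.

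The same comparison in pye-1 asks how pye-1 roots respond to 24 h without iron. All 5 uptake genes rose. AT3G12900 was at least 137-fold higher than its +Fe control level (adjusted p = 2.61e-06). AT3G58060 rose by 4.54 ± 0.43, but by 3.75 without pye-1 replicate 1 with iron, whose signal lay under the control level, and by 3.86 with signals raised to that level. AT3G07720 rose by 3.85 ± 0.21, BGLU42 by 2.32 ± 0.13 and AT3G13610 by 1.33 ± 0.20. Of the 11 regulator probe sets 5 rose and 6 did not pass, with the same counts adjusted over the list alone: BHLH101 by 3.52 ± 0.28, AT1G47400 by 2.72 ± 0.19, AT1G74770 by 2.1 ± 0.31 and 2.1 ± 0.17, and AT1G18910 by 1.18 ± 0.16. PYE had a change of 0.65 ± 0.27 (adjusted p = 0.545). The uptake list rose as a set (adjusted p = 1.24e-24, and 0.00434 with an estimated correlation). With signals raised to the control level its mean was 3.69, 3.49 in replicate 1 and 3.89 in replicate 2 (adjusted p = 2.84e-27, and 0.00354 with an estimated correlation). The regulators rose with a mean of 1.13, 1.08 in replicate 1 and 1.17 in replicate 2 (adjusted p = 2.06e-12, and 0.0117 with an estimated correlation).

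Of the 5 phenylpropanoid and coumarin genes, 2 rose, both shared with the uptake list, and all 5 adjusted over the list alone. They rose as a set (adjusted p = 1.96e-12, and 0.00886 with an estimated correlation). With signals raised to the control level the mean was 1.98, 1.79 in replicate 1 and 2.17 in replicate 2 (adjusted p = 6.93e-13, and 0.0193 with an estimated correlation), and HCT, CCR2 and AT1G28680 had changes of 0.41, 0.62 and 0.44. Oxidative stress genes rose as a set of 4, with a mean of 0.67, 0.76 in replicate 1 and 0.58 in replicate 2 (adjusted p = 4.12e-04, and 0.0468 with an estimated correlation, or 0.0682 with the block as well). Its 1 member past the threshold was AT2G21640, a marker of mitochondrial oxidative stress, which rose by 1.79 ± 0.31, and 2 members passed adjusted over the list alone. GSTU25, NDB2 and STZ had changes of 0.51, 0.31 and 0.07. The 4 photosynthesis genes fell as a set with a mean of -0.54, -0.45 in replicate 1 and -0.63 in replicate 2 (adjusted p = 0.00175, but adjusted p = 0.0557 with an estimated correlation). None of them was past the threshold alone, and 2 were when adjusted over the list alone. The root hair markers EXPA18 and EXPA7 had changes of -0.58 and -0.19, of which EXPA18 passed with the block (adjusted p = 0.0160). The other 5 lists gave adjusted p from 0.120 to 0.508.

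ATPMEPCRB rose by 5.70 ± 0.63, AT3G61930 by 4.17 ± 0.14, AT5G38820 by 3.19 ± 0.21 and AT4G19370 by 2.88 ± 0.26 in pye-1. For ATPMEPCRB the signal in pye-1 replicate 2 with iron lay under the control level, and it rose by 5.18 with signals raised to that level and by 4.38 without that array. AT4G10270, of a family induced by wounding and low oxygen, rose by 3.40 ± 0.49, but by 2.77 without pye-1 replicate 1 with iron, whose signal lay under the control level, and by 2.90 with signals raised to that level. Decreases were called for CYP718 (-2.2 ± 0.30), the peroxidases AT3G49960, AT1G34510 and AT4G26010 (-1.83 ± 0.34, -1.79 ± 0.33 and -1.05 ± 0.12), AT2G41810 (-1.70 ± 0.24) and AT3G61870 (-1.43 ± 0.23). AT1G21440, AT5G54040, the glycosyltransferase family gene AT3G46700 and AT5G50310 also fell, with changes of -1.26, -1.06, -0.92 and -0.72. Unnamed probe sets chosen after their values were seen were probe-253502_at, at least 85.7-fold higher, probe-257689_at, which rose by 4.27, probe-254818_at, which fell by 2.56 (-1.73 and -3.39 without pye-1 replicate 1 or 2 without iron), and probe-254107_at, which reached the control level without iron and was at least 3.52-fold lower.

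In pye-1, 167 probe sets changed, 135 higher and 32 lower, and the changes in replicate 1 and 2 correlated at 0.42 across all tested probe sets. The replicate block gave 422, 269 higher and 153 lower. Without pye-1 replicate 2 with iron, or pye-1 replicate 1 or 2 without iron, 101, 87 and 109 passed, and 99 without the intensity trend. The rises of AT3G12900, AT3G58060, AT3G07720, BGLU42, BHLH101, AT1G47400, ATPMEPCRB, AT3G61930, AT5G38820 and AT4G19370 and the falls of CYP718 and AT4G26010 held in each of the 8 fits that left out an array. The other genes named here each missed the threshold in at least one such fit, except for the AT1G74770 probe set with the smaller error, and the highest adjusted p was 0.350, for AT5G50310 without pye-1 replicate 2 with iron. AT5G50310 and probe-254107_at also missed with signals raised to the control level (adjusted p = 0.0505 and 0.0566).

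The overlap of the iron responses of wild type and pye-1, which share no array, was large. Iron genes such as AT3G12900, AT3G58060, AT3G07720, BGLU42, BHLH101, AT1G47400 and AT1G74770 were called in both. In all, 66 probe sets were higher in both genotypes, where independent lists of these lengths would share 0.755, and 20 were lower in both, against 0.133. Both calls of a probe set use the same error estimate from all 8 arrays, so the lists are not independent and these expected counts are only a reference. The replicate block gave 117 and 57. Across the 155 called in wild type, 144 had the same sign in pye-1, and 146 of the 167 called in pye-1 had the same sign in wild type. AT1G19530 and AT1G33055 were called in both genotypes in opposite directions. The call of AT1G33055 in wild type was lost without any 1 of 6 arrays (adjusted p up to 0.363). That of AT1G19530 was lost in pye-1 without any 1 of the 4 pye-1 arrays (up to 0.206), and in wild type without replicate 1 with iron or either replicate without iron (up to 0.193). Across all probe sets, which are not independent replicates, the 2 responses correlated at 0.424.

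**Figure D2:**
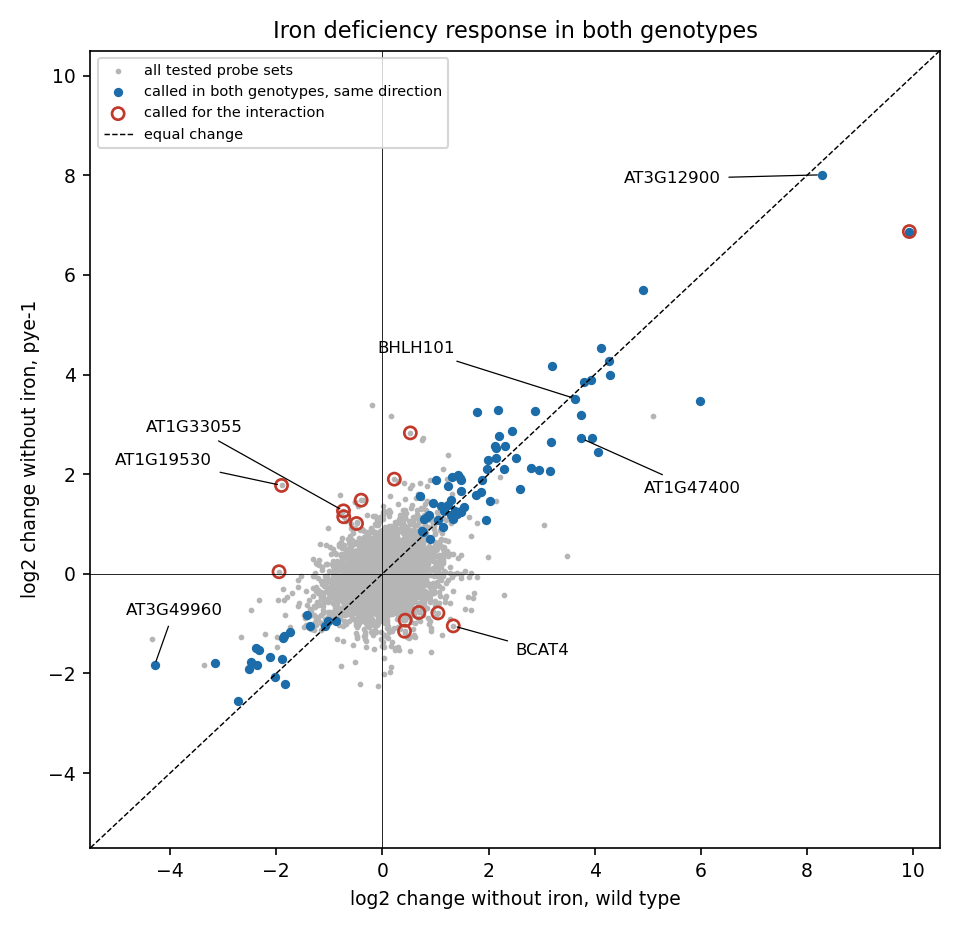
Log2 change without iron in pye-1 (vertical axis) against wild type (horizontal axis) for each of the 15922 tested probe sets (grey points). Filled points were called in the same direction in both genotypes, rings mark the 14 called for the interaction, and the dashed line marks equal change.

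With iron present, pye-1 and wild type were compared to see what the pye-1 mutation changes in roots that are not short of iron. AT1G47400, the iron-signalling peptide gene, was higher in pye-1 by 2.39 ± 0.19 (adjusted p = 4.99e-04), by 2.32 in replicate 1 and 2.47 in replicate 2. GH3.3, an enzyme of the family that conjugates jasmonate and auxin to amino acids, was higher by 1.52 ± 0.21 (adjusted p = 0.0466). GI, the clock-associated gene GIGANTEA, was lower, with a change of -1.56 ± 0.19 (adjusted p = 0.0213), -1.16 in replicate 1 and -1.96 in replicate 2. BHLH101 had a difference of 1.43 ± 0.28 (adjusted p = 0.229, and 0.0262 with the block). Its signal in wild-type replicate 2 with iron lay under the control level. The difference was 1.32 with signals raised to that level and 0.90 without that array. AT3G47650, the gene next to PYE in the TAIR10.1 assembly, had a difference of -1.59 ± 0.24 (adjusted p = 0.0630, and 0.00463 with the block). The unnamed probe sets probe-259871_at and probe-251109_at, chosen after their values were seen, were higher by 3.68 ± 0.19 and 1.06 ± 0.14, and probe-249910_at was lower, with a change of -0.84 ± 0.12. Probe set probe-253502_at also passed, but it was at or below the control level in both groups, so no fold is given, and with signals raised to that level it did not pass (-0.34, adjusted p = 0.998).

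With iron, 10 probe sets differed between the genotypes, 8 higher and 2 lower in pye-1, and 3 of these name a single gene. The replicate block gave 55, 27 higher and 28 lower. The uptake list had 0 of 5 members past the threshold (1 adjusted over the list alone, AT3G12900, which was at the control level in both groups) and the regulators 1 of 11 (3 adjusted over the list alone, 2 higher and 1 lower, PYE). No list shifted in this comparison, with adjusted p from 0.700 to 0.875 for the 10 lists tested by camera in limma, and no list passed with an estimated correlation or with the block. The regulator list includes PYE, the mutated gene itself, which pulls its mean down. Its test therefore does not show whether the other regulators shifted. Mean and median differed in sign for the uptake list (0.13 and -0.05), the regulators (0.22 and -0.02), the phenylpropanoid list (0.15 and -0.11) and the list of zinc, copper and manganese transport (0.03 and -0.21). The test pointed downward for the phenylpropanoid and zinc lists, and with signals raised to the control level the uptake and phenylpropanoid means were -0.13 and -0.16. Leaving out wild-type replicate 1 or 2 or pye-1 replicate 2 with iron gave 17, 5 and 6 probe sets, the fit of the 4 arrays alone 3, and the exclusion of the dimmest 50% of probe sets 5. AT1G47400 and probe-259871_at passed in each fit that left out an array, while GI missed without wild-type replicate 2 or pye-1 replicate 2 with iron (adjusted p up to 0.160), probe-251109_at missed in 6 of the 8 fits (up to 0.203), and GH3.3 and probe-249910_at in all 8 (up to 0.230).

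Without iron, the comparison of pye-1 with wild type asks what the pye-1 mutation changes in iron-deficient roots. Of 19 probe sets in a list of low-oxygen response genes, compiled after the leading genes had been seen, 5 were higher in pye-1. The 19 include the genes that prompted the list, so this count is no test of it. The 13 members not noticed beforehand were higher as a set, with a mean of 0.50 (adjusted p = 6.42e-08, and 0.0278 with an estimated correlation, but 0.0544 with the block as well). AT4G10270 was higher in pye-1 by 3.13 ± 0.49 (3.09 with signals raised to the control level), AT1G19530 by 2.99 ± 0.33, AT1G33055 by 1.99 ± 0.14 and AT4G27450 by 1.65 ± 0.14. The peroxidase AT3G49960, which fell in wild type without iron, was higher by 2.19 ± 0.34, but by 1.57 without wild-type replicate 1 without iron, whose signal lay under the control level, and by 2.08 with signals raised to that level. AT2G05540, of a glycine-rich protein family, was higher by 2.19 ± 0.25, the rubredoxin-like AT5G51010 by 1.97 ± 0.19, the small heat shock protein family gene AT5G51440 by 1.90 ± 0.22, AT1G69050 by 1.80 ± 0.28 and AT2G21640 by 1.74 ± 0.31. Apart from PYE, BCAT4, an aminotransferase of methionine-derived glucosinolate synthesis, was lower, with a change of -2.1 ± 0.24, as were GI at -1.73 ± 0.19, AT3G47650 at -1.72 ± 0.24, AT1G21440 at -1.5 ± 0.22, the glucosyltransferase AT2G31790 at -1.33 ± 0.20 and the oxygenase family gene AT1G14120 at -1.01 ± 0.18.

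Of the regulators in the comparison without iron, AT1G47400 was higher in pye-1 by 1.36 ± 0.19 (adjusted p = 0.0104), and BHLH101 had a difference of 1.32 ± 0.28 (adjusted p = 0.109, 0.0145 with the block, and 0.0476 with signals raised to the control level). None of the 5 uptake genes passed, also adjusted over the list alone, with AT3G12900 at 0.94, AT3G13610 at 0.38, BGLU42 at 0.14, AT3G07720 at 0.12 and AT3G58060 at 0.04. Among 11 regulator probe sets, 1 was higher and 1, PYE, lower, or 3 and 1 adjusted over the list alone. PYE, the mutated gene itself, also enters each set test of the regulators below. SAPX was higher by 0.81 ± 0.12. The oxidative stress list was higher as a set, with a mean of 0.64, 0.65 in replicate 1 and 0.63 in replicate 2 (adjusted p = 0.00198). It was not with an estimated correlation (adjusted p = 0.195) or without pye-1 replicate 1 without iron (adjusted p = 0.0700, mean 0.56). Its 4 members were AT2G21640, which passed, also adjusted over the list alone (1 member), and STZ, NDB2 and GSTU25, with differences of 0.49, 0.19 and 0.15. With the block the uptake list and the regulators passed too (adjusted p = 0.0342 and 0.0435), against 0.351 and 0.384 with the block and an estimated correlation together. The uptake list also passed with signals raised to the control level (adjusted p = 0.0270, and adjusted p = 0.235 with an estimated correlation). The other 9 lists gave adjusted p from 0.0695 to 0.809 without the block. Photosynthesis, root hair and dividing-cell markers gave no call: the photosynthesis and dividing-cell lists had means of -0.25 and -0.27, and EXPA18 and EXPA7 differences of -0.07 and 0.03.

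Among unnamed probe sets, chosen after their values were seen, probe-259871_at was higher in pye-1 without iron by 5.56 ± 0.19 (adjusted p = 3.78e-07) and probe-251109_at by 3.05 ± 0.14, while probe-258321_at and probe-254687_at were lower, with changes of -1.91 and -1.89. In all, 74 probe sets differed, 52 higher and 22 lower in pye-1, and the replicate-wise differences correlated at 0.32 across all tested probe sets. The replicate block gave 273, 159 higher and 114 lower. Leaving out wild-type replicate 1 or 2 without iron gave 20 and 39, leaving out pye-1 replicate 1 or 2 without iron 41 and 45, and the fit without the intensity trend 26. AT1G19530, AT1G33055, AT4G27450, AT5G51010, AT2G05540, GI, probe-259871_at and probe-251109_at passed in each of the 8 fits that left out an array. PYE, BCAT4, AT3G47650, AT1G21440, AT2G31790, AT1G14120, AT4G10270, AT3G49960, AT5G51440, AT1G69050, AT2G21640, SAPX, AT1G47400, probe-258321_at and probe-254687_at each missed without at least one of the 4 arrays compared, most often wild-type replicate 1, with adjusted p of up to 0.470 for AT1G14120.

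**Figure D3:**
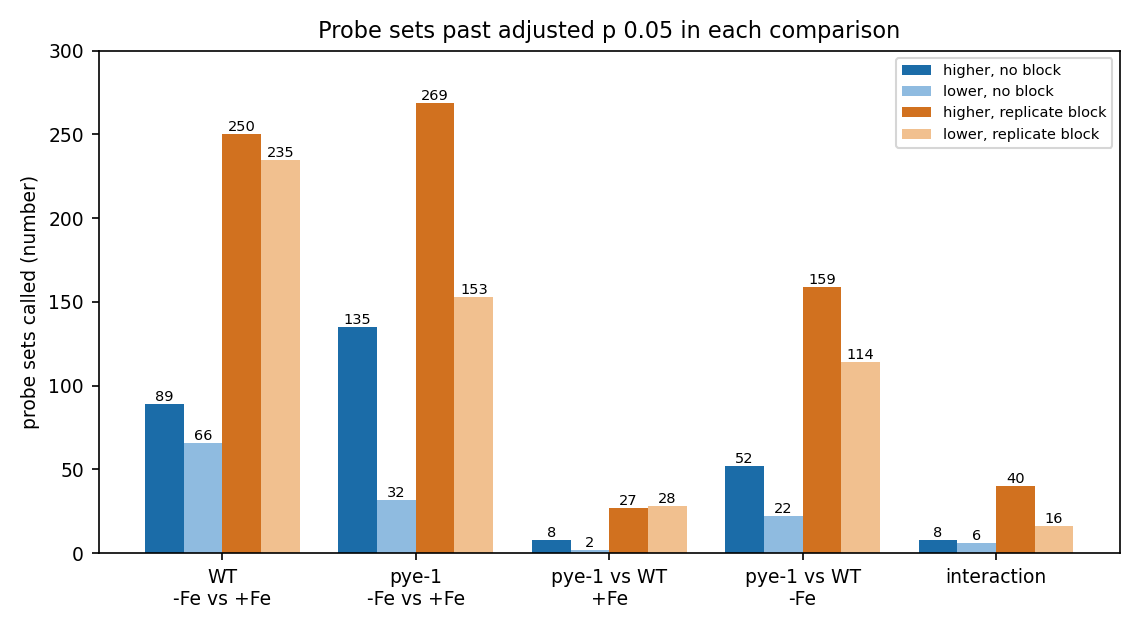
Number of probe sets past adjusted p 0.05 (vertical axis) in each of the 5 comparisons (horizontal axis), higher and lower, without and with replicate number as a block. The lowest counts without the block are 10 for pye-1 against wild type with iron and 14 for the interaction.

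The interaction asks whether the response to iron deficiency differed between the genotypes, as the change in pye-1 minus the change in wild type. AT1G19530 fell by 1.90 in wild type and rose by 1.77 in pye-1, an interaction of 3.67 ± 0.47 (adjusted p = 0.0222), or 3.08 and 4.27 without wild-type replicate 1 or 2 with iron. AT1G33055, of the same low-oxygen list, fell by 0.73 in wild type and rose by 1.26 in pye-1 (interaction 2.00 ± 0.20, adjusted p = 0.0106). AT5G51010 and AT4G27450 rose in pye-1, with interactions of 1.87 ± 0.27 and 1.5 ± 0.19. BCAT4 rose by 1.34 in wild type and had a change of -1.05 in pye-1 (interaction -2.38 ± 0.34, adjusted p = 0.0416). Of the iron regulators, BHLH101, AT1G47400 and PYE did not pass, with interactions of -0.11 ± 0.40, -1.03 ± 0.27 (adjusted p = 0.521) and -0.59 ± 0.39. For AT3G12900 both responses are bounds, so no interaction is given.

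The interaction was called for 14 probe sets, 8 higher and 6 lower, and for 13 with signals raised to the control level, where probe-253502_at did not pass. It was called for 56 with the replicate block, 40 higher and 16 lower. None of the 10 lists tested with limma's camera shifted (adjusted p from 0.217 to 0.993, also none with an estimated correlation). With signals raised to the control level the uptake and phenylpropanoid lists passed, with means of 0.45 and 0.42, in which the responses of AT3G12900 are bounds (adjusted p = 0.0267 for both, but adjusted p = 0.377 for both with an estimated correlation). The mean of the regulators, with the mutated gene PYE included, was -0.11. For photosynthesis the mean was -0.15, the median 0.05 and the test's direction upward. The limma fit without the intensity trend called 0 probe sets, as did the fits without wild-type replicate 1 or pye-1 replicate 1 or 2 without iron, while 915 had an unadjusted p under 0.05 in the fit with the trend. Leaving out wild-type replicate 1 or 2 with iron, wild-type replicate 2 without iron or pye-1 replicate 1 with iron gave 9, 8, 4 and 7, and 8 passed with no filter or without the dimmest 50% of probe sets. Each of the 5 genes that passed missed the threshold without wild-type replicate 1 without iron, with AT1G33055 at an adjusted p of 0.0810, AT1G19530 at 0.142, AT4G27450 at 0.149, and AT5G51010 and BCAT4 at 0.210. The rise of BCAT4 in wild type missed without any 1 of the 4 wild-type arrays (adjusted p up to 0.194).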

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

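The low-oxygen list, the RNA quality, RNA degradation and poly(A) tests, the replicate-wise values of unseen members, the raising of signals to the control level, and the fit with replicate block and estimated correlation together were chosen after the results had been seen. The test of the interaction itself called 14 probe sets, of which 13 kept the call with signals raised to the control level. The change in pye-1 was above that in wild type for AT1G19530 by 3.67 ± 0.47 (adjusted p = 0.0222), AT1G33055 by 2.00 ± 0.20 (0.0106), AT5G51010 by 1.87 ± 0.27 (0.0416) and AT4G27450 by 1.5 ± 0.19 (0.0248). The same held for the unnamed probe-258487_at by 2.30 ± 0.24 (0.0106), probe-251109_at by 1.99 ± 0.20 (0.0106), probe-259871_at by 1.88 ± 0.26 (0.0416) and probe-248332_at by 1.68 ± 0.25 (0.0499). It was below that in wild type for BCAT4, with an interaction of -2.38 ± 0.34 (0.0416), probe-251524_at with -1.83 ± 0.23 (0.0211), probe-249867_at with -1.57 ± 0.18 (0.0145), probe-263706_s_at with -1.46 ± 0.22 (0.0499) and probe-252607_at with -1.36 ± 0.16 (0.0145). For probe-253502_at the value was -3.06 ± 0.37 (0.0172), but it compares +Fe signals at or below the control level in both genotypes, so it is no measured difference in response. It was -0.49 with a pseudocount (0.886) and 0.65 with signals raised to the control level (0.902).

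Low-oxygen response genes averaged 8.1 and 8.0 log2 units on the 2 pye-1 arrays without iron and 7.07 to 7.42 on the other 6. Selection of the genes first noticed is argued against as the whole cause, since 13 members not noticed beforehand had a mean difference of 0.497, 11 of them above 0 (adjusted p = 6.42e-08, and 0.0278 with an estimated correlation, but 0.0544 with the block as well). A single array is argued against as the whole cause, since the mean difference of these 13 was above 0 in both replicate numbers, 0.536 and 0.458. Their standard errors over members, 0.171 and 0.128, treat genes as replicates and do not measure the spread between arrays. Over all 19 members, the genes that prompted the list included, the differences were 1.03 and 0.893. In the mean of these 19, the 2 pye-1 arrays with iron lay at 7.07 and 7.39. RNA quality cannot be told apart: the mean GAPDH ratio of the 2 arrays, 1.40, lay inside the range of 1.28 to 1.58 of the other 6, but the ubiquitin ratio of pye-1 replicate 1 without iron, 3.42, lay above their 2.60 to 3.28. In pye-1, the 13 unseen members rose without iron by 0.482 on average (camera adjusted p = 3.04e-05, but 0.0620 with an estimated correlation). Their mean was -0.04 for the response in wild type and -0.03 for pye-1 against wild type with iron. The interaction had a mean of 0.523 (camera adjusted p = 3.19e-05, but 0.0625 with an estimated correlation). Also open, as untested hypotheses, are the oxygen supply or handling of the 2 pye-1 samples without iron, for which no value exists here, and a response of pye-1 roots to iron deficiency.

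AT3G47650, the gene next to PYE in the TAIR10.1 assembly, was lower on all 4 pye-1 arrays than on any wild-type array. Cross-hybridisation with the PYE transcript is argued against, because in wild type without iron the rise of PYE exceeded the change of AT3G47650 by 1.34 ± 0.364. A drop across the neighbourhood is argued against by the other 10 measured genes within 10 places of PYE. Their lower median change, without iron, was 0.0604, above the bound of -0.5, and the standard error of their mean was 0.0822. On the side of AT3G47650 these were only AT3G47670, AT3G47680 and MAG2. AT3G47630, on the other side of PYE, had differences of 0.21 with iron and 0.70 without, neither past the threshold. An effect of the insertion on the adjacent gene, or a linked difference in background, stays open and was not tested.

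The arrays split by replicate number: 1445 probe sets differed between replicate 1 and 2, 803 higher and 642 lower on replicate 2, with psbT, rpl20 and psaI among those with the largest rise. RNA degradation, which raises all ratios of 3' to 5' signal, is argued against as the whole cause: from replicate 1 to 2 the log2 ratio moved by 0.217 ± 0.0440 for actin, up in all 4 groups, by -0.218 ± 0.0590 for ubiquitin, down in all 4, and by -0.0598 ± 0.0990 for GAPDH. Harvest at another time of day cannot be told apart, because only 3 clock genes were measured (mean absolute difference 0.107, against a median of 0.148 for all probe sets). Labelling of more RNA without a long poly(A) tail on replicate 2 arrays cannot be told apart either: 64 organelle genes had a mean difference of 0.303 ± 0.0407, 50 of them higher, but the set did not pass with an estimated correlation. No biological explanation of this split other than time of day was tested.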

How the results depend on the processing

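The fit with the replicate block together with an estimated correlation, and the raising of signals to the control level, were chosen after seeing the data. With replicate number as a block, 485 probe sets passed for the iron response in wild type, 422 in pye-1, 55 for pye-1 against wild type with iron, 273 without iron and 56 for the interaction, and the overlap rose to 174. The block also took PYE with iron (-1.84) past the threshold (adjusted p = 0.0171), and gave 3 list shifts without iron, and it changed no other call among these summary results. Without the intensity trend the counts were 90, 99, 26 without iron and 0 for the interaction, where limma gave 915 at an unadjusted p under 0.05 with the trend, and PYE with iron (-1.84) passed (adjusted p = 0.0234). Leaving out the lowest 50% gave 5 with iron and 8 for the interaction, and no filter 8 and 1 list shift for the interaction. With only the 4 arrays compared, 3 passed with iron. Lists that shifted with the block and an estimated correlation were 2 in wild type, 3 in pye-1 and 0 without iron, and 0 without iron with the estimated correlation alone. With single arrays left out, counts ran from 83 to 173 in wild type, 87 to 154 in pye-1, 5 to 17 with iron, 20 to 88 without iron and 0 to 10 for the interaction. PYE without iron ran from -2.52 to -2.35, and list shifts without iron from 0 to 3. A lone array left in its group is assumed to vary like the others. Without a replicate term, changes that involve this group also carry part of the difference between replicate numbers, so these fits do not isolate the effect of single arrays. The cause was not tested, except that fewer arrays or probe sets enter by construction where some were left out. Also by construction, the block takes the difference between replicate numbers, called for 1445 probe sets, out of the residual. Each replicate number holds 1 array per group, so the log2 changes are the same with and without the block. The rise in counts therefore comes from the error estimate and its degrees of freedom, whose shares were not separated. With signals raised to the control level, 2 lists shifted without iron and 2 for the interaction, and probe-253502_at changed sign with iron (-0.34) and for the interaction (0.65), since its +Fe signals are at or below that level. Of 106 called values of named genes and of unnamed probe sets singled out, 43 kept their call in every alternative, and these 2 changed sign. Between 71.0% and 82.6% of probe sets were above the control level on an array, which limits what can be said of the dimmest.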

Other observations

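The glucosinolate and clock lists, the gene family scan and the organelle set were compiled or chosen after results had been seen, as was a minimum of 3 genes for the glucosinolate test, so no test of a list is given that includes the genes that prompted it. Of 4 genes of glucosinolate synthesis, BCAT4 rose in wild type without iron by 1.34 ± 0.24, and GSTU20 had a change of 1.00 ± 0.21 (adjusted p = 0.0686, and 0.0269 with the block). Without iron, BCAT4 (-2.1 ± 0.24) and AT2G31790 (-1.33 ± 0.20) were lower in pye-1 than in wild type, and GSTU20 had a difference of -1.10 ± 0.21 (adjusted p = 0.0729, and 0.0242 with the block) and UGT74B1 of -0.06. The hypothesis that the pathway is lower as a set was tested on AT2G31790 and UGT74B1, the 2 members recorded as not noticed beforehand. AT2G31790 is itself 1 of the 7 named genes called lower in pye-1 without iron, so these 2 members give no independent test. Their mean was -0.694 (adjusted p = 0.0105, but adjusted p = 0.136 with an estimated correlation), which meets the criterion set before it was seen, a mean below 0 that passes at the preset correlation. It is left open because AT2G31790 carries the mean and 2 genes are under the minimum added afterwards.

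Of 3 clock-associated genes, GI was lower in pye-1 on both media, at -1.56 ± 0.19 with iron and -1.73 ± 0.19 without. The other 2 did not pass on either medium: COR27 had differences of -0.48 and -0.69, and AT4G33980 of -0.72 and 0.02. The hypothesis of a shift of the clock as a set was tested on these 2, which had not been noticed beforehand. By signed camera, the mean of the 2 genes was -0.596 with iron (adjusted p = 8.15e-04, but adjusted p = 0.143 with an estimated correlation). Without iron it was -0.336 (adjusted p = 0.147, and 0.323 with an estimated correlation). These 2 genes are too few to decide the hypothesis.

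Among 21 gene families formed from the names given, none shifted past the threshold by camera in limma in any comparison, with the lowest adjusted p at 0.0808 and 0.0784 for the iron responses of wild type and pye-1, 0.177 and 0.0822 for pye-1 against wild type with and without iron, and 0.468 for the interaction. The 69 probe sets matched by locus to the organelle genomes, which do not cover all organelle genes measured, had mean changes of -0.03 in wild type and -0.10 in pye-1 without iron. The limma fit called 0 of them in the 5 comparisons.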
